A study of Mus musculus with 6 samples.

How the data were processed

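The series holds 6 single-colour (Cy3) Agilent arrays of mouse ooplasts and blastocysts. Per the labels' protocols, total RNA was extracted on columns without DNase treatment, amplified and labelled. Per the file headers, spot intensity was extracted with Agilent Feature Extraction, version 9.5 per the submitters' processing notes, and probes were placed on mm8. Per the file headers, the deposited processed signal was background-subtracted by spatial detrending, given a surrogate value near background and not scaled between arrays. The authors' deposited value table holds log2 values. Set against the scanner signals, each column had a rank correlation of 1 with its own array and lay within 0.00075 of a quantile normalization of the processed signal on the linear scale, so its scale, centring and direction are known. Each column's median was 6.25. All of its columns were mapped to samples.

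Values were log2 of the processed signal minus each array's 75th percentile over non-control spots. Control spots were dropped, and a spot flagged as an outlier was left out of its probe's mean unless all of the probe's spots were flagged. Saturated spots were kept (0 on the ooplast arrays, at most 13 on a blastocyst array). A probe was kept if well above background on every array of at least 1 compared group, and the probe with the highest mean over the 6 arrays stood for its gene. This rule favours bright probes. Names came from a RefSeq gene table (GRCm38.p6), used for names only because the files use mm8. Of 41174 probes, 24375 were named by accession, 6301 carried a current symbol, 2426 were renamed from a synonym and 8072 kept the file's name, giving 27597 names, 8942 of them with over 1 probe. No genome of the files' build was used here, so exon and UTR positions are not given, and coordinates are those of the files.

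The 4 blastocyst arrays were compared by age and all 6 arrays by stage with age as a term, using limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg, threshold 0.05). The labels call replicates biological but name no animals, so p-values measure the spread between these samples. The ooplast groups have 1 array each and no test was run. There, genes at least 2-fold apart were counted and a list's median was placed among 10000 random lists matched in 20 bins of expression. Lists of at least 5 measured genes were tested with camera (preset correlation 0.01), and again with an estimated correlation and with fry, which asks whether a list's genes move 1 way on balance. Of the 17 lists, none shared a gene. They covered oocyte-specific and maternal-effect genes, M-phase, cohesin, oxidative phosphorylation, antioxidant, DNA repair, chromatin, pluripotency, trophectoderm, primitive endoderm, imprinted, ribosomal protein, glycolysis, proteasome, apoptosis, heat shock and cumulus genes. Groups, lists, tests and most alternatives were fixed before the data were examined.

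Named genes followed a fixed rule. For age in blastocysts these were the 12 higher and 12 lower genes with the largest change past the threshold and without overlap, filled with genes of unadjusted p under 0.05. For ooplasts they were the 12 highest and lowest measured on both arrays, and for stage the 12 highest and lowest past the threshold, each with up to 4 bounds per direction. Up to 4 members per list, 10 lineage and maternal genes, and all sex-linked genes were added. Clone, accession and predicted names were passed over, and 1 gene that the rule names for ooplasts is not reported here.

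The files show 2 slides. Slide 1 held both ooplast arrays and replicate 1 of each blastocyst group, and slide 2 held replicate 2 of each blastocyst group. The correlation of replicate deviations between the blastocyst groups was 0.17 over 2 pairs, too few to show that the numbers pair the samples.

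Each test was run first on simulated data with 200 genes changed by known folds, drawn with the real means and residual spread. For age in blastocysts (15971 genes) 0% of genes changed 2-, 4- or 8-fold and 30% changed 16-fold were recovered. For stage (15604 genes) the shares were 0%, 44%, 70% and 88%. In the data 11620 genes passed for stage, far more than were changed in the simulation. The Benjamini-Hochberg cutoff depends on that share, so the simulated stage shares do not describe recovery in the data. The simulated blastocyst shares likewise hold only for the number of genes changed there. Camera called a shifted list and did not call an unshifted one in both simulations. Genes were drawn independently in every simulation, so none checks lists whose genes move together. In the stage data the estimated correlation was 0.24 for oxidative phosphorylation and 0.40 for ribosomal protein genes. In the ooplast simulation (12289 genes) a shifted list of 40 lay at the 100 percentile and an unshifted one at the 4.92 percentile. Alternatives were quantile normalization, scaling on probes detected on all arrays, normexp with offset 50, the authors' values, no or stricter filters on dim probes, the mean of probes, each array left out, blocks, age and stage terms, a trend, and thresholds. Figures were drawn with matplotlib 3.10.9.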

Results

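RNA from mouse oocyte cytoplasm and from blastocysts was measured on 6 single-colour Agilent whole-genome arrays, 1 sample per array. An ooplast is an oocyte whose chromosomes have been removed. A blastocyst is the embryo at the stage of an outer trophectoderm and an inner cell mass. The samples came from young or climacteric (reproductively aged) B6C3 F1 females. There was 1 array of young ooplasts, 1 of climacteric ooplasts, 2 of young blastocysts and 2 of climacteric blastocysts, and the series' design text calls the replicates biological. The labels used here do not say how the blastocysts were produced. Of 43379 non-control spots, 42.4% were well above background on the young and 42.2% on the climacteric ooplast array. The blastocyst arrays had 49.9% (young, replicate 1), 52.7% (young, replicate 2), 57.3% (climacteric, replicate 1) and 54.9% (climacteric, replicate 2). The 75th percentile of the signal was 235 and 238 units on the ooplast arrays and between 721 and 1111 on the blastocyst arrays. Across the 10907 genes well above background on all 6 arrays, Pearson's r between blastocyst arrays was 0.962 to 0.983, and between the ooplast arrays 0.927. These are correlations across genes, and genes are not independent replicates. The number of arrays limits the precision of each value below. All levels are log2 signal minus the array's 75th percentile.

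The first comparison set the 4 blastocyst arrays against the 2 ooplast arrays, with age as a term. Fabp3 and Cdx2 were among the genes with the largest rise in blastocysts. Fabp3, a fatty acid binding protein, stood at 8.74 ± 0.10 (SD, n = 4) in blastocysts and -1.60 ± 0.97 (SD, n = 2) in ooplasts, a 1299-fold difference. Its probe lies on chromosome 4 from 129817668 to 129817727 in mm8, the build of the files. Cdx2, the transcription factor that specifies trophectoderm, was 531-fold higher in blastocysts, with log2 9.05 ± 0.55 (SE) and adjusted p = 2.51e-05 (limma, Benjamini-Hochberg). Its probe lies on chromosome 5 from 147611320 to 147611379. The endocytic receptor gene Lrp2 was 1159-fold higher. The creatine transporter gene Slc6a8 was 664-fold higher, the peptide transporter gene Slc15a2 was 445-fold higher and the nucleoside transporter gene Slc28a3 was 429-fold higher. Grtp1, Prps1, Prxl2b, Cdc5l, Nup133 and Plet1 were between 439-fold and 873-fold higher. Of these 12 genes Prxl2b, Cdc5l and Plet1 were well above background on both ooplast arrays. The other 9, Fabp3, Cdx2 and Lrp2 among them, were so on 1, so that their folds depend on a signal at background on the other ooplast array, such as -4.27 for Lrp2. Leaving out 1 ooplast array gave 396-fold or 3391-fold for Lrp2, 228-fold or 1238-fold for Cdx2 and 819-fold or 2058-fold for Fabp3, and 1 array left out moved 13 of the 24 genes named with exact values, rising and falling, by over 1.5 times. Other probes of these genes gave smaller rises, such as log2 1.21 for Slc15a2 and 1.61 for Plet1. The Slc15a2 probe was above background on all 6 arrays. That of Plet1 was so on 4, so its value depends in part on background. Where probes had to be well above background on all 6 arrays, that second Slc15a2 probe stood for the gene and the call was lost. The galectin gene Lgals4 and the homeobox gene Rhox5 were not well above background on either ooplast array. Lgals4 was at least 2494-fold and Rhox5 at least 1498-fold higher in blastocysts. Lgals6 was at least 1705-fold and Wfdc2 at least 1646-fold higher. Here and below, "at least" sets the brighter group's mean against the lowest signal among well measured probes on each dim array, or the probe's own signal if higher.

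**Figure D1:**
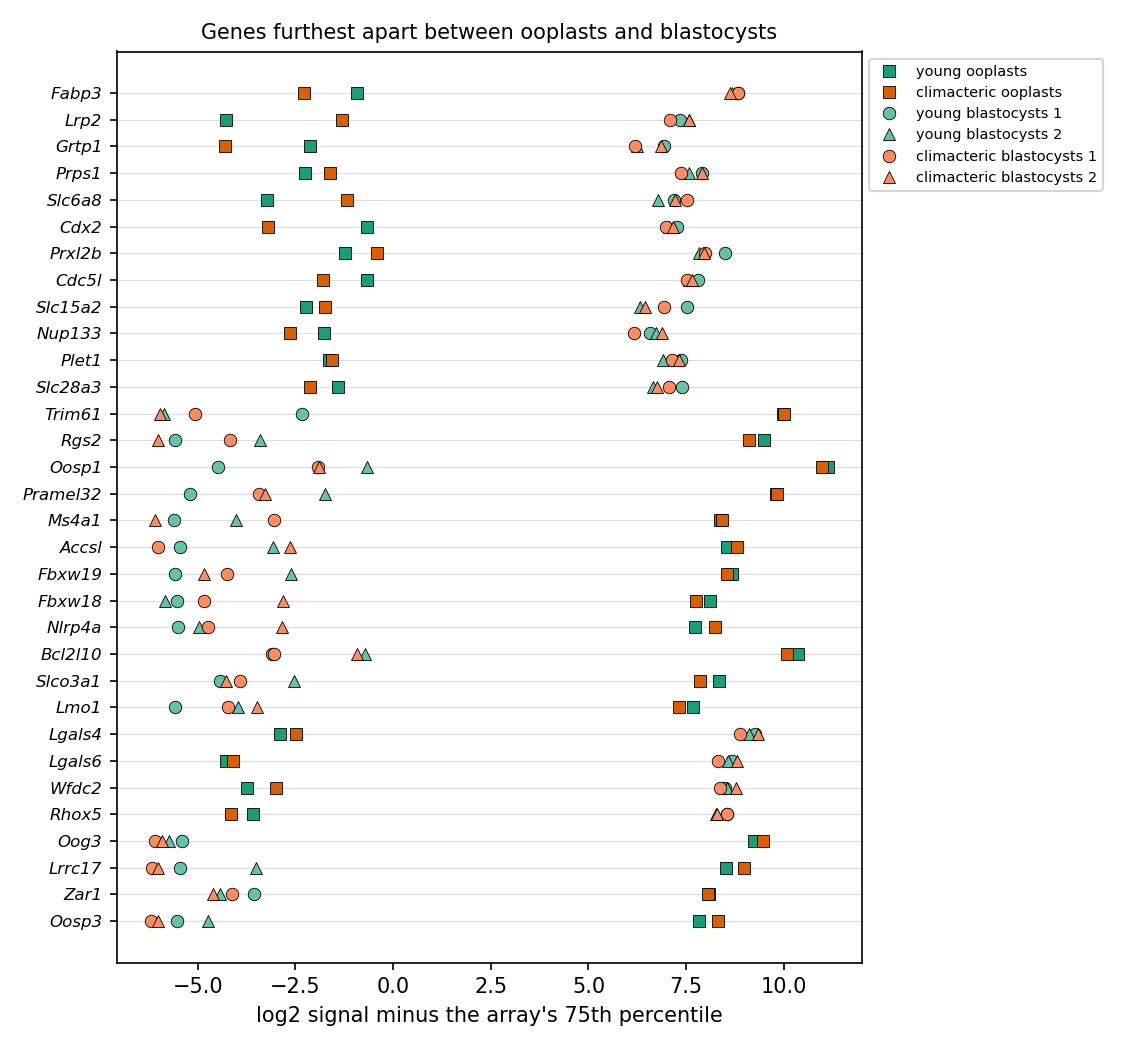
Signal of the genes furthest apart between ooplasts and blastocysts (vertical axis) on each of the 6 arrays, as log2 signal minus the array's 75th percentile (horizontal axis). Each point is 1 array, and the blastocyst arrays of Fabp3 average 8.74 against -1.60 on the ooplast arrays.

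Genes of the oocyte fell in blastocysts. Trim61 stood at 9.99 ± 0.02 (SD, n = 2) in ooplasts and -4.81 ± 1.70 (SD, n = 4) in blastocysts, where it was well above background on 1 of the 4 arrays (adjusted p = 3.31e-05). Its probe lies on chromosome 8 from 67942041 to 67942100. Oosp1, which encodes an oocyte-secreted protein, fell (log2 -13.30 ± 0.98, SE), and a second probe stood at -13.46. Bcl2l10, a member of the Bcl2 family, fell (-12.17 ± 0.82, SE). Rgs2, a regulator of G-protein signalling, fell (-14.10 ± 0.74, SE), and was well above background on 1 blastocyst array. Pramel32, Ms4a1, Accsl, Fbxw19, Fbxw18, Nlrp4a, Slco3a1 and Lmo1 fell, with values from -13.22 to -11.82, and 6 of these 8 were well above background on 1 blastocyst array. For those 6, Trim61 and Rgs2, the other 3 blastocyst arrays were not well above background, so the sizes and order of these falls depend on the background level. A second probe of Ms4a1 (-6.42) gave a smaller fall, as did that of Nlrp4a. Oog3, Lrrc17, Zar1 and Oosp3 were not well above background on any blastocyst array. Oog3 was at least 8552-fold lower there, Lrrc17 at least 5542-fold, Zar1 at least 3520-fold and Oosp3 at least 3497-fold. Among genes fixed in advance, Gdf9, an oocyte growth factor, fell (-9.96 ± 0.29, SE), as did Zp3, a zona pellucida protein gene (-6.65 ± 0.50). Mos, a kinase of meiotic arrest, was at least 25.1-fold lower and Nlrp5 at least 10.2-fold lower. Gata6 rose by 5.06 ± 0.25 (SE), and Nanog was at least 3.76-fold higher. Gata4 fell (-1.68 ± 0.44, SE, adjusted p = 0.013). Without the young ooplast array it stood at -0.94, and within slide 1 at -1.53, and neither passed the threshold. Pou5f1 differed by 0.25 ± 0.39 (SE, adjusted p = 0.57) and Dppa3 by -0.38 ± 0.31 (SE, adjusted p = 0.29), neither past the threshold.

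Of 17 gene lists fixed in advance, 9 differed between the stages by limma's camera with a preset correlation. With an estimated correlation none of the 9 passed: the adjusted p was 0.24 for the oocyte list, 0.25 for oxidative phosphorylation, cumulus, trophectoderm, proteasome and antioxidant genes, 0.29 for glycolysis and 0.31 for ribosomal proteins and heat shock. By the preset correlation, the oocyte-specific and maternal-effect genes were lower in blastocysts (camera adjusted p = 4.38e-13): 38 of 40 measured members fell, while Khdc3 rose by 3.79 ± 0.25 (SE). Among those that fell, Btg4, Rfpl4 and Obox5 were not well above background on any blastocyst array, and were at least 1115-fold, 1106-fold and 346-fold lower there. Of 16 cumulus and granulosa cell markers 10 fell, among them Cyp19a1 (-7.50 ± 0.32) and Inhba (at least 9.51-fold lower), and 2 rose, Amhr2 and Inhbb (adjusted p = 0.012). Of 30 trophectoderm genes 25 rose (adjusted p = 1.38e-06), such as Id2 (at least 518-fold higher), Krt18 (8.25 ± 0.30) and Krt8 (7.67 ± 0.24), and Ets2, Tjp1 and Ascl2 fell. Of 76 oxidative phosphorylation genes 70 rose (adjusted p = 1.22e-14), with Cox7b at 6.23 ± 0.29 and Cyc1 at 6.09 ± 0.27, and Uqcrc2 fell (-0.62 ± 0.24). Of 77 ribosomal protein genes 65 rose (adjusted p = 3.64e-13), with Rps15 at 6.21 ± 0.24, and Rpl21 and Rpl37 fell. Of 38 proteasome genes 26 rose and 6 fell (adjusted p = 0.000409), with Psmc2 at 6.43 ± 0.27. Of 38 antioxidant genes 26 rose and 6 fell (adjusted p = 0.000591). The metallothionein gene Mt1 rose by 7.89 ± 0.30 and Txnip, an inhibitor of thioredoxin, fell (-5.03 ± 0.31). Of 27 glycolysis genes 18 rose (adjusted p = 0.0088), among them the glucose transporter gene Slc2a3 (at least 322-fold higher), and Bpgm, Ldhb and Pdk3 fell. Of 35 heat shock and unfolded protein response genes 20 rose, among them Hspa8 (5.37 ± 0.28), and 8 fell, among them Atf6 and Ern1 (adjusted p = 0.030). The cumulus list also missed the threshold where probes had to be well above background on all 6 arrays, and the heat shock list with the young arrays alone.

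**Figure D2:**
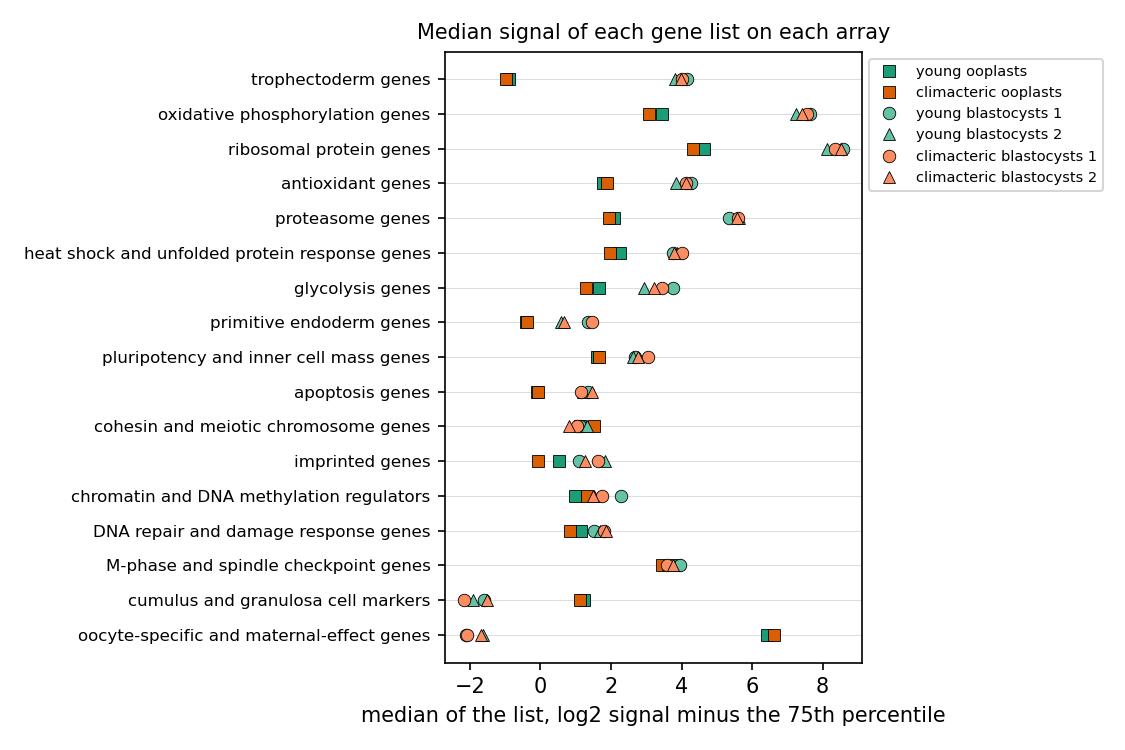
Median log2 signal minus the 75th percentile (horizontal axis) of each gene list (vertical axis) on each of the 6 arrays, 1 point per array. The trophectoderm list lies at -0.89 on the young and -0.98 on the climacteric ooplast array and between 3.81 and 4.14 on the blastocyst arrays.

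The other 8 lists were not called by camera. Of 48 M-phase and spindle checkpoint genes 12 rose and 26 fell, with Wee2 at least 38.1-fold lower and Cdc23, above background on 1 ooplast array, at 6.29 ± 0.41 (SE; adjusted p of the list = 0.18). Of 65 chromatin and DNA methylation regulators 18 rose and 25 fell, with Tet3, a 5-methylcytosine oxidase abundant in oocytes, at -7.72 ± 0.40 and Cbx3 at 6.76 ± 0.27 (adjusted p = 0.78). Of 53 DNA repair genes 24 rose and 20 fell (adjusted p = 0.62), and of 33 cohesin and meiotic chromosome genes 15 rose and 11 fell (adjusted p = 0.44). The median of the DNA repair list was -0.29 while its mean was 0.47 and camera's direction up. Across scalings the medians of the DNA repair list (-0.49 to 0.27), the chromatin list (-0.28 to 0.047) and the imprinted list (-0.29 to 0.13) changed sign. Among 26 pluripotency genes 12 rose and 6 fell, with Tfcp2l1 at least 103-fold higher and Tcl1 at -7.61 ± 0.28 (adjusted p = 0.11). Among 23 primitive endoderm genes 13 rose and 5 fell (adjusted p = 0.071). That list passed without the young ooplast array, without 3 of the 4 blastocyst arrays in turn, and with slide as a block. Among 26 imprinted genes 11 rose and 7 fell (adjusted p = 0.44), and among 34 apoptosis genes 16 rose and 7 fell (adjusted p = 0.11). Adjusted over the list alone, the counts for all 17 lists were the same except 66 rising ribosomal protein genes, 7 falling antioxidant genes, 25 rising and 21 falling DNA repair genes and 15 rising apoptosis genes.

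In all, 11620 of 15604 genes tested (74.5%) passed an adjusted p of 0.05, 5538 of them higher and 6082 lower in blastocysts. At least 2-fold, 5283 were higher and 5389 lower. The split was 5610 higher and 14335 lower with no filter on dim probes, and 3206 and 4901 with probes well above background on all 6 arrays. Background lay lower on the blastocyst arrays after scaling. Ddx3y, above background on no array, had a probe at -4.37 and -4.18 in ooplasts and between -6.16 and -5.41 in blastocysts. Of 280 olfactory receptor genes (Olfr) tested, 122 fell and 16 rose. How many lower calls are of background size was not tested. A further description counts 2267 genes above background in blastocysts and on no ooplast array, and 497 the other way. The blastocyst arrays had 49.9% to 57.3% of spots well above background, against 42.2% and 42.4% on the ooplast arrays. These counts are therefore not on an equal footing. With slide as a block 10770 genes passed, and within slide 1, which held both ooplast arrays and the first replicate of each blastocyst group, 9947 passed. The median of all genes was -0.26 and lay between -0.45 and -0.14 across scalings, so differences of that size have no settled direction.

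The second comparison asked what maternal age changed in the ooplast and had 1 array per group, so it carries no test and no replicate check. Ribosomal protein and oxidative phosphorylation genes were the lists that lay lower in climacteric ooplasts than random lists of like expression. The median of 75 ribosomal protein genes was -0.28 (climacteric minus young), at the 0.01 percentile of 10000 random lists, and 53 of the 75 were lower. Rpl8 stood at -2.60 and Rpl13a at -1.86. The median of 69 oxidative phosphorylation genes was -0.20, at the 0.295 percentile, with 44 lower, Cox7c at -1.99 and Cox6c at -1.41. The ribosomal percentile was at most 0.02 and the oxidative phosphorylation percentile at most 1.87 under every scaling tried, while their medians reached 0.0025 and 0.099, so the position relative to other genes held and the sign did not. Random lists hold unrelated genes, while these genes move together. Their estimated correlation in blastocysts was 0.57 (ribosomal) and 0.28 (oxidative phosphorylation), so the percentiles can overstate a shift. The ribosomal list median was 4.64 in young and 4.33 in climacteric ooplasts. It was 8.57 and 8.13 on the young blastocyst replicates, and 8.34 and 8.53 on the climacteric ones. For oxidative phosphorylation genes these were 3.46 and 3.08, 7.63 and 7.25, and 7.55 and 7.42. The other 15 lists lay within the central 95%, from the 5.84 percentile for heat shock genes to the 87.6 percentile for imprinted genes. The oocyte-specific and maternal-effect genes had a median of -0.0063 over 40 members, 1 of them at least 2-fold higher (Astl, 1.32) and 1 lower (Nobox, -1.10). The medians of the remaining lists were 0.063 for M-phase, -0.013 for cohesin, -0.018 for antioxidant, -0.015 for DNA repair, 0.17 for chromatin, -0.17 for pluripotency and 0.22 for trophectoderm genes. They were 0.0019 for primitive endoderm, 0.33 for imprinted, -0.083 for glycolysis, -0.11 for proteasome, 0.20 for apoptosis, -0.12 for heat shock and -0.17 for cumulus genes, beside 0.15 for all genes.

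**Figure D3:**
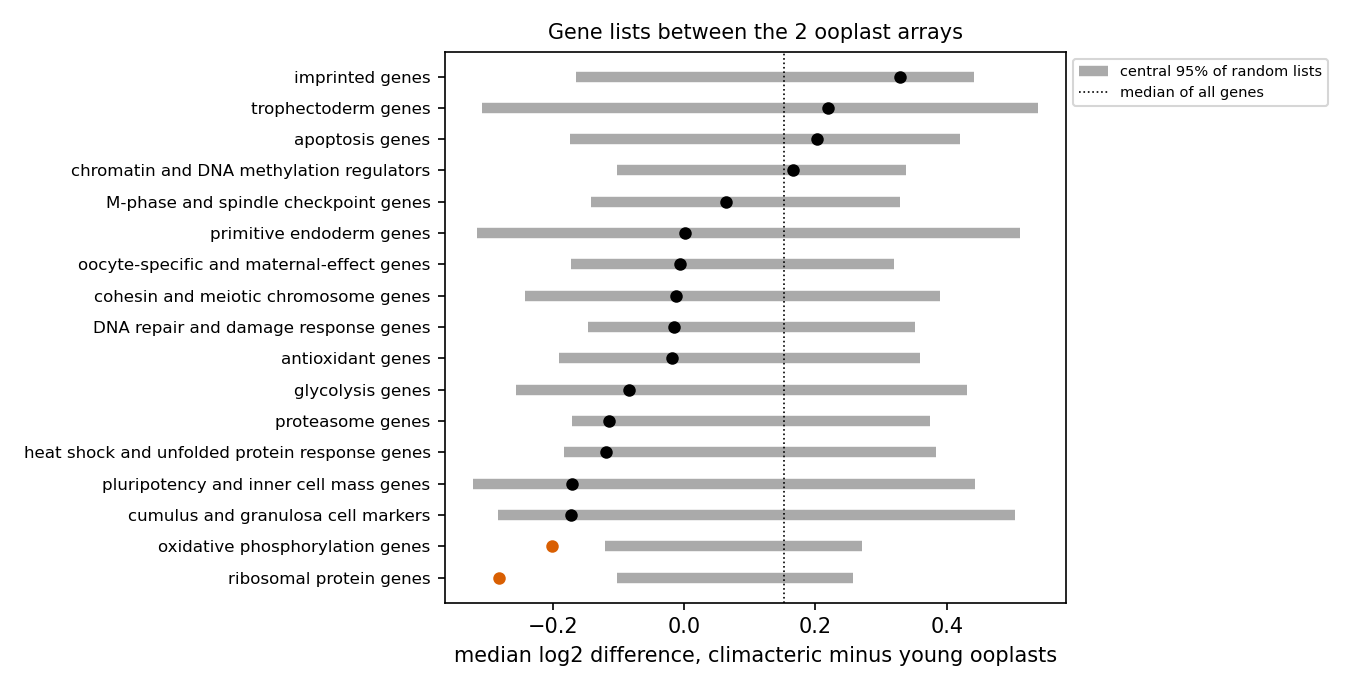
Median log2 difference, climacteric minus young ooplasts (horizontal axis), of each gene list (points), with the central 95% of 10000 random lists of matched expression (grey bars) and the median of all genes (dotted line). The ribosomal protein list at -0.28 and the oxidative phosphorylation list at -0.20 lie left of their bars.

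Single genes differed more. Timp2, a metalloproteinase inhibitor gene, was 35.0-fold higher in climacteric ooplasts; its probe lies on chromosome 11 from 118117922 to 118117981. Fcer1g, the Fc receptor gamma chain gene of leucocytes, was 11.8-fold higher, and its second probe, not above background on the young array, was at least 12.3-fold higher. Lyz2, the macrophage lysozyme gene, was at least 73.1-fold higher, with its second probe at 0.24 and not above background. Higher too were Ccl5, a chemokine gene, by at least 33.5-fold, Ptges by at least 30.3-fold and Zfp536 by at least 27.7-fold. Of 24 further macrophage markers, 7 were well above background on the climacteric ooplast array alone and 0 on the young one alone. On both arrays 8 were above background. A marker was counted if any of its probes was above background. Coro7, Vstm2l, Grk6, Tln2, Dnajc30, Trim54, Arhgap10, Polr3e, Ypel3 and Bag6 were 6.02-fold to 13.5-fold higher. Other probes of Polr3e (1.20), Grk6 (0.17 and 0.30) and 2 of Bag6 (1.80 and 0.69) lay above 0, and those of Coro7 (-0.056), Tln2 (-2.15), Arhgap10 (-1.06) and 1 of Bag6 (-7.50) below. Ccdc88a, which encodes an actin-binding protein, was 918-fold lower in climacteric ooplasts (chromosome 11, 29404215 to 29404274). Its second probe stood at -2.20 and was above background on 1 of the 6 arrays. Ano3 was 770-fold, Ece2 481-fold, Amot 427-fold and Myoz3 423-fold lower. Synpo2, Glra2, Olfr969, Smim24, Klk1b21 and Cntln were 326-fold to 405-fold lower, Olfr763 at least 966-fold, Atf7ip2 at least 545-fold, Npnt at least 409-fold and Ubr1 at least 342-fold. Second probes of Ece2 (-0.0049), Synpo2 (0.16) and Amot (3.11) did not show these falls, nor did other Cntln probes (0.71 and -0.35). Those of Amot and Cntln were above background on only 2 of the 6 arrays each, so their values may rest on background.

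Of 12289 genes well above background on both ooplast arrays, 2117 (17.2%) were at least 2-fold apart, 905 higher and 1212 lower in climacteric ooplasts. The corresponding share between replicate arrays was 11.3% for young (14492 genes) and 11.1% for climacteric blastocysts (15800 genes). Those arrays are of another stage and had more signal, so the gap is not a measure of age. The split depended on the scaling: it was 1373 higher and 979 lower when scaled on probes detected on all arrays, 1324 and 1146 after quantile normalization, 449 and 903 after normexp, and 1328 and 1162 in the authors' values. Relative to the median of all genes, it was 607 and 1490. Of 2671 genes with 2 or more such probes, the differences on the 2 brightest correlated at r = 0.043 across genes, against 0.52 for the stage difference over the same genes. Of them, 86 were at least 2-fold apart the same way on 2 probes.

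The third comparison asked the same of blastocysts, 2 climacteric arrays against 2 young ones, and each gene named here missed the adjusted threshold. Armcx1 stood at -2.22 ± 0.04 (SD, n = 2) in climacteric and -5.65 ± 0.19 (SD, n = 2) in young blastocysts, where it was not well above background, so at least 2.51-fold higher. Klhl35 was at least 4.45-fold, Mbl2, the mannose-binding lectin gene, at least 4.49-fold, Elapor1 at least 5.02-fold, Aoc1 at least 3.92-fold, Magi2 at least 3.76-fold, Entpd3 at least 3.37-fold, Hsd17b13 at least 2.80-fold and Krt23 at least 2.29-fold higher. Syce1, Muc3 and Arhgap27 were well above background on 1 young array and 12.1-fold, 10.9-fold and 10.4-fold higher. Without the first young replicate, the array at background, these were 3.16-fold, 2.59-fold and 3.48-fold. Tcta was at least 9.19-fold, the calcium-binding S100g at least 5.70-fold and Cst12 at least 2.83-fold lower. Ptgs1 was well above background on 1 climacteric array and 13.9-fold lower, and 5.98-fold against that array alone. Fzd5, Clcn6, Dmbt1, H2-Ab1, Kctd17, Cd248, Tfap4 and Esam were 12.5-fold to 22.1-fold lower in climacteric blastocysts. Without the second young replicate these were 3.63-fold (Kctd17) to 7.05-fold (H2-Ab1) lower. All 8 of these had their highest signal on the young ooplast array, such as 8.57 for Fzd5 against 4.48 in climacteric ooplasts. Of the named higher genes, Mbl2 (7.34 in young and 7.02 in climacteric ooplasts), Klhl35, Magi2 and Muc3 were also brightest on an ooplast array, and the rest were not. Second probes of Cd248 (0.047), Tfap4 (0.31) and H2-Ab1 (-0.096), above background on 6, 4 and 3 of the 6 arrays, did not show a fall. Those of Fzd5 (0.74) and Clcn6 (1.68) were above background on only 2 and 1 arrays, so they cannot decide. Over 3643 genes with 2 or more probes above background, the age differences on the 2 brightest correlated at r = 0.16 across genes. No gene passed an adjusted p of 0.05 by limma among 15971 tested, and the smallest adjusted p was 0.24. At an unadjusted p under 0.05 there were 864 (456 higher and 408 lower in climacteric blastocysts), where chance gives 798.55. Leaving out the first or the second young replicate gave 1 gene each, and 1 array left out moved the fold of 20 of the 24 named genes by over 1.5 times.

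**Figure D4:**
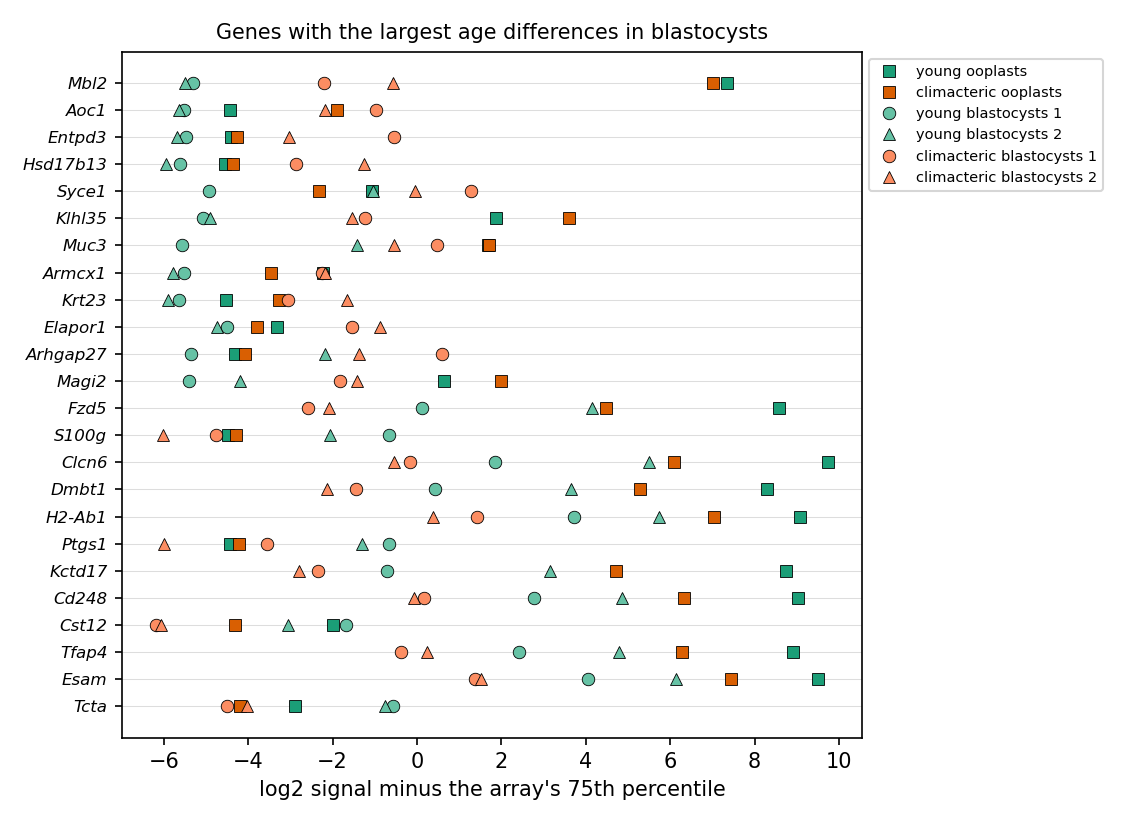
Signal of the 24 genes named for the age comparison in blastocysts (vertical axis) on each of the 6 arrays, as log2 signal minus the array's 75th percentile (horizontal axis), 1 point per array. Fzd5 stands at 8.57 on the young and 4.48 on the climacteric ooplast array, and Armcx1 averages -2.22 in climacteric and -5.65 in young blastocysts.

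Among the lists, the 24 primitive endoderm genes lay furthest apart between climacteric and young blastocysts, with a median of 0.42 and 18 members above 0, among them Sox7 (2.76 ± 1.00, SE), Gata4 (0.83 ± 0.39) and Pth1r (1.67 ± 0.99). No list passed by camera, and the smallest adjusted p, for that list, was 0.33 (0.99 with an estimated correlation). It passed without the first young replicate, and did not without any other blastocyst array. The 46 M-phase and spindle checkpoint genes had a median of -0.15 with 34 members below 0 (adjusted p = 0.38). The adjusted p of 31 cohesin genes, at a median of -0.14, was 0.66, and for the other 14 lists it was 0.95 or 0.96. Their medians were 0.030 for oocyte, -0.039 for oxidative phosphorylation, 0.049 for antioxidant, 0.027 for DNA repair, 0.12 for chromatin, 0.013 for pluripotency and -0.032 for trophectoderm genes. They were -0.068 for imprinted, -0.0084 for ribosomal protein, 0.0014 for glycolysis, -0.039 for proteasome, -0.053 for apoptosis, -0.071 for heat shock and -0.0018 for cumulus genes. Adjusted over the list alone, Oas1e of the oocyte list (-1.94 ± 0.30, SE) and Has2 of the cumulus list (at least 3.30-fold lower) fell, and no member of the other lists passed. Of the lineage genes, Pou5f1 differed by 0.52 ± 0.41, Nanog by 0.34 ± 0.44, Cdx2 by -0.090 ± 0.29 and Gata6 by -0.17 ± 0.28. Dppa3 differed by -0.027 ± 0.36, Zp3 by -0.60 ± 0.56 and Gdf9 by 0.48 ± 0.33 (all SE), and Mos and Nlrp5 were not above background.

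Replicate number and slide coincide in the blastocysts, and with slide as a block 0 genes and 0 lists passed. With normexp and that block together, a setting chosen after seeing the data, 297 genes (59 higher and 238 lower in climacteric blastocysts) and 1 list passed. Within slide 1, 2086 genes were at least 2-fold apart between climacteric and young blastocysts, within slide 2, 1670, and 451 the same way on both. No chance figure was computed for that 451. Across genes, the age differences on the 2 slides correlated at r = 0.18. The groups did not overlap for 30.0% of genes, where chance gives 33.3%. In simulated data with the observed spread, the test without a block recovered 0% of genes changed 8-fold and 30% of those changed 16-fold among 15971 genes. These shares hold only for the number of genes changed there, on which the Benjamini-Hochberg cutoff depends. By limma at an unadjusted p under 0.05, 98% of the genes changed 8-fold were recovered.

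Whether age moved genes the same way in ooplasts and blastocysts was asked across the 10907 genes above background on all arrays, with 1 correlation between the age differences and 2 with differences between replicates as references. Spearman's rho between the age differences was 0.32 and Pearson's r 0.41, and 61.3% of genes lay on the same side of the medians. Across genes, the ooplast difference also correlated with differences between replicates, at rho = -0.19 for young blastocysts (replicate 2 minus 1) and -0.14 for climacteric ones. The rho was 0.24 with the age difference on slide 1 and 0.26 on slide 2. It was 0.19 without the second young replicate and 0.20 without the first climacteric one. The same probe stood for a gene at both stages, so the agreement may be of probes rather than of genes.

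The sex-linked genes were read on every array. Xist, the RNA that silences an X chromosome, was well above background on all 4 blastocyst arrays on all 4 of its probes, the brightest between 0.72 and 1.97. On the ooplast arrays 1 Xist probe was above background, in climacteric ooplasts at -1.15. Tsix was above background on both climacteric blastocyst arrays alone. The Y-linked genes Ddx3y, Eif2s3y, Usp9y, Uty, Zfy2 and Sry were not well above background on any of the 6 arrays. The Kdm5d probe and 1 of 2 Zfy1 probes were above background on all 6 arrays, including the ooplasts, which come from females.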

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

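No test in this part was chosen after its result was seen. Among the genes named for age, Arhgap10 moved in opposite directions at the 2 stages. Its signal was log2 2.72 higher in climacteric than in young ooplasts and -1.18 in climacteric minus young blastocysts, with both climacteric arrays below both young ones. The difference between the stages was not tested, and a second Arhgap10 probe stood at -1.06 in ooplasts. Over 49 sets of 4 blastocyst values, from the genes named for stage and the list medians, no array lay apart from the other 3 by Dixon's criterion, where chance would place about 1 set in 20.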

How the results depend on the processing

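The setting that joins normexp with the replicate block, slide 1 alone, the centring on the median and the settings on several probes were chosen after seeing the data. For age in blastocysts the count stayed at 0 under every scaling, filter and probe rule, with the replicate block and with a trend. It was 864 at an unadjusted p under 0.05, 0 to 1 without single arrays, and 297 (59 higher) with normexp and the replicate block together. The cause was not tested. Where an array left out leaves a group with 1, that array is assumed to vary like the others. Lists past the threshold were 0, except 1 with no filter, 1 with normexp and the replicate block, and 0 to 1 without single arrays, each time the primitive endoderm list. For stage the count was 8107 of 10907 genes with the all-array filter (fewer genes tested), 19945 with no filter (more genes tested), 9906 to 11387 without single arrays and between 9589 (young arrays only) and 11906 in the other settings. Lists past the threshold were 8 with the all-array filter and with young arrays only, 12 with climacteric arrays only, 14 with no filter, 0 with an estimated correlation, 16 by fry and 9 to 11 without single arrays. Genes at least 2-fold apart in ooplasts numbered 1352 with normexp, 4631 with no filter, 530 at 4-fold, 4997 at 1.5-fold and 86 on at least 2 probes. The 2 ooplast lists kept their place in every setting. The rho between age differences was 0.17 with no filter, 0.22 with probes above background on at least 1 array, 0.23 on second brightest probes, and 0.19 to 0.33 without single arrays. Reversals were Mre11a (-2.17) and Sfmbt2 (-0.98) for stage with the all-array filter, Xrcc2 (3.03) in ooplasts with no filter, and Bag6 (-0.61) and Peg3 (0.19) in ooplasts with the mean of probes. For Bag6 and Peg3 other probes disagree, and for the rest the cause was not tested. Of the values of single named genes, 1415 for age in blastocysts kept direction and side of the threshold and 30 newly passed, and for stage 1974 kept them, while Slc15a2 (1 setting) and Gata4 (3 settings) lost their calls. In ooplasts 640 moved by less than the spread between replicates and 57 by more. The all-array filter equals the main rule in ooplasts and was not run there. In blastocysts slide equals replicate number, so no separate slide block was run. No paired analysis was possible for ooplasts because each group has 1 array. Signal over background limits depth most in ooplasts, where 42.2% to 42.4% of spots were well above background.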

Other observations

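Gene families were grouped by symbol, and the search, with its limits on family size and share, was set up after the stage values and these families were seen, so its count is not independent of them. Of 204 families with at least 8 genes tested, 9 had at least 70% of their genes past the threshold between ooplasts and blastocysts and none of those going the other way, against a mean of 0.92 and at most 4 in 1000 shufflings of the family labels. The Ndufa, Ndufb, Ndufs and Psma families have members in lists already described, as does the Nlrp family, whose Nlrp2, Nlrp4f, Nlrp5 and Nlrp14 are in the oocyte list, so their moves are in part the same result. All 9 measured Emc genes, of the endoplasmic reticulum membrane complex, rose in blastocysts, as did 7 of 8 Chchd genes and 6 of 8 Cct genes, of the cytosolic chaperonin. Of 14 Nlrp genes 12 fell, and of 8 synaptotagmin genes (Syt) 7 fell. The median of the Syt genes was -1.94. Background also lay lower on the blastocyst arrays, and how much of the Syt fall is background was not tested. The olfactory receptor and macrophage tests below were set before their results were seen, and all other tests below after.

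On the climacteric ooplast array 202 probes were at least 8-fold brighter than on the young one. A set of 631 probes was at least 8-fold dimmer there, with a median of 5.66 on the young and -1.07 on the climacteric array. On the blastocyst arrays the median of these 631 was -1.32 and -0.37 (young, replicates 1 and 2) and -1.75 and -1.56 (climacteric, replicates 1 and 2). A spatial defect is argued against, since adjacent pairs of such spots were 0.914 times the number their density gives. A change in each gene's whole transcript pool is also argued against, since 247 other probes of the same genes had a median difference of 0.13 (quartiles -0.53 and 0.51). Genomic DNA would raise silent genes on the young array, but olfactory receptor probes outside the set were above background 0.794 times as often there, and 0.818 times with the 11 in the set counted too. A signal specific to single probes, such as a particular transcript end or a labelled by-product, may remain, and age itself stays untested with 1 array per group.

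The age differences in ooplasts and blastocysts went together across genes, with the same probe standing for a gene at both stages. Differences on a gene's 2 brightest probes correlated at only r = 0.043 in ooplasts and 0.16 in blastocysts. The agreement may thus be of probes rather than of genes, which was not tested. The probes far apart between the ooplast arrays do not carry this alone, since Pearson's r was 0.37 without genes at least 8-fold apart. Without the second young blastocyst replicate rho was 0.19, close in size to the -0.19 seen with a difference between replicates. Whether that array alone carries the agreement is therefore not settled. A gradient of sample quality or of residual oocyte RNA was not tested as a source of the agreement. The oocyte-specific and maternal-effect list gave no sign of more oocyte RNA at 1 age. Its median age difference was 0.030 in blastocysts (13 members above and 13 below 0) and -0.0063 in ooplasts (20 and 20). Sample quality and maternal age cannot be told apart here.

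Leucocyte genes were brighter on the climacteric ooplast array (Lyz2, Ccl5, Fcer1g), as was Timp2, and on the first climacteric blastocyst replicate Lyz2 (5.07) and Ctss (1.73) were bright too, against values below -3.7 on the other 3 blastocyst arrays. Signal of a single probe is argued against for Fcer1g, whose second probe was higher by at least 3.62 (log2), and stays open for Ccl5, whose second probe was higher by at least 0.71, and for Lyz2, whose second probe was above background on neither array. A list of 24 macrophage markers was set before the test, without those 4. A marker counted as above background if any of its probes was. On the climacteric ooplast array alone 7 were above background, and on the young one alone 0. This excess of 7 leaves macrophages in the climacteric ooplast sample as a hypothesis. Ctss stood at 2.51 against -4.06, C1qc at 2.19 against -4.40 and Tyrobp at 0.38 against -3.17. Ccl6 stood at only -1.65 against -2.29. Other probes of Adgre1, Aif1 and Mpeg1 were above background on neither ooplast array. Of the markers above background on both arrays, Cd68 (1.46), Csf1r (1.45), Itgb2 (0.95) and Cd14 (0.78) were higher in climacteric ooplasts, while Ccl4 stood at 1.62 against 1.86, Cd74 at -0.64 against -0.14 and C1qb at -0.17 against 0.066, the brightest Ms4a7 probe at 1.33 against 6.60, and 9 markers, C1qa, Laptm5 and Ptprc among them, were above background on neither ooplast array. In all, 8 markers were above background on both ooplast arrays and 17 on a blastocyst array, and age itself stays open and untested.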
